A study of Mus musculus with 8 samples.

How the data were processed

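Two-colour cDNA arrays had been hybridised with Cy3-labelled cDNA from pools of 3 neonatal hearts and Cy5-labelled cDNA of a common reference, per the labels. The reference had been prepared at once for all arrays from adult tissues of both sexes, among them aorta, brain, heart, kidney, liver, lung, gonads, spleen and stomach. Mice were of the C57BL background, wildtype or null for connexin43, with 4 pools per genotype. Dyes were the same on all 8 arrays, so that dye bias stays in levels against the reference and cancels between genotypes. Replicates were pools of different hearts per the labels, and p-values measure the spread between pools rather than between single animals.

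The deposited values are log ratios of both dyes per spot. Their unit was taken as log2 from the deposited values themselves: differences between spots of 1 block of 598 rows matched the log of a ratio of whole numbers up to 120, within 1.5e-09, in 7497 of 30866033 cases with base 2, against 266 with base e and 795 with base 10. All 944 repeated values of an array fell within 1 of its 48 blocks, so that each block carries its own scaling. The scanner software, background correction, spot filter and the scaling the authors applied are not given in the sources used here. Deposited array medians were 0.21, -0.10, -0.31 and -0.11 for wildtype replicates 1 to 4 and -0.34, -0.28, -0.08 and -0.24 for null replicates 1 to 4. The direction of the ratio is not stated in the labels and was taken from a rule: the median of sarcomere genes had to lie above that of genes of other adult tissues on every array for heart to be the numerator. It did so on 8 of 8 arrays, with medians of 0.64 to 1.01 for the first and -2.80 to -1.82 for the second.

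Probes were named through the platform annotation, whose symbols can be old. Of 28704 probes 18511 had 1 gene symbol, 937 had several and 9256 are unnamed here; no gene was named from a probe with several symbols. Of the named probes 18267 matched the GRCm38.p6 gene table by gene number, and 0 received a newer symbol. Each array was centred on its median. Probes of 1 symbol with values on at least 3 arrays of each group were averaged by a fit of probe and array effects, which equals the plain mean when no value is missing. A feature was tested if it had values on at least 3 arrays of each group. This left 11804 features, 7603 with 1 gene symbol and 4201 without a single symbol; 3035 were averages of several probes, and 8238 had values on all 8 arrays. Probes of 1 gene did not always give like values: across the 3035 genes, which are not independent replicates, the differences on 2 probes correlated with r = 0.271 and had opposite signs for 39.9%.

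Null minus wildtype was fitted with lmFit and eBayes without a trend in limma 3.58.1 under R 4.3.3, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. Gja1 was also tested with an exact two-sided permutation test. Gene lists and cell type markers with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over 26 lists, and again with an estimated correlation and with fry. The estimated correlation needs complete values, so that it ran on the 5677 named genes measured on all arrays. Fry tests whether the genes of a list move on balance one way and does not compare the list with other genes. Adjusted p-values of lists come from limma. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

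The groups, tests, lists, markers, direction rule and the rule for named genes were chosen before the data were examined. That rule names Gja1, then in each direction the 10 genes with the largest change past the threshold whose groups do not overlap, with open places filled by the smallest unadjusted p, and up to 4 members per list by p-value. Since no gene passed, all 20 places were filled by p-value. Alternatives fixed then were no centring, quantile normalization, scaling to equal spread, stricter and looser limits on missing values, single probes, the probe with the fewest missing values, robust eBayes, array weights, other thresholds, limma treat, each array left out in turn and the replicate number as a block. With an array left out, a probe needed values on all 3 arrays left in that group, so that some gene averages lost a probe. For genes with several probes, a value without 1 array can therefore mix the loss of a probe with that of the array. The labels give both genotypes the numbers 1 to 4 without saying that a number marks a shared litter or day. Alternatives added after seeing the data were centring within blocks, a median over spots with a value on all arrays, a plain mean of probes, a correction for the trend of the difference on the mean ratio, and the preset correlation on the genes measured on all arrays.

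The scripts were tested on simulated data built on the 11804 features of the null against wildtype comparison, with 200 changed features in each of 10 runs. They called 49.0% of 1.5-fold, 96.8% of 2-fold, 99.8% of 3-fold and 100% of 4-fold changes, and 4.82% of calls were false. A list shifted by 0.2 on the log2 scale was called in 100% of 20 runs, in which 1 call of an unchanged list occurred. In the simulation genes vary independently. The rates hold for 200 features changed at once and do not carry over to data with fewer changes. They cannot show that a count of 0 excludes 2-fold changes. In the real data Gja1 was 1.94-fold lower and had a limma adjusted p of 0.340.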

Results

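Gene expression was measured in hearts of neonatal mice that lacked connexin43 and in hearts of wildtype neonatal mice. Connexin43, encoded by Gja1, forms the main gap junction channels between working heart muscle cells. Each of 8 arrays carried cDNA from a pool of 3 hearts, with 4 pools per genotype, and each was hybridised together with 1 common reference made from adult mouse tissues. Values are log2 ratios of heart over reference, centred so that the median of each array is 0. Of 28704 spots, wildtype replicates 1 to 4 had a value at 12971, 21246, 18378 and 23929, and null replicates 1 to 4 at 17879, 18849, 20212 and 19042. Wildtype replicate 1 had the lowest median rank correlation with the other arrays, 0.576 over spots with a value on all arrays, against at least 0.663 for each other array. The number of arrays limits the precision of every difference given here, and the median standard error of a log2 difference was 0.14.

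The first question was whether the deleted gene separated the arrays as labelled. Gja1 fell in the null hearts, from a mean log2 ratio of 1.03 ± 0.21 (SD, n = 4) in wildtype to 0.08 ± 0.25 (SD, n = 4), a 1.94-fold lower level. The wildtype arrays read 1.04, 1.31, 0.99 and 0.79, and the null arrays -0.29, 0.25, 0.12 and 0.22, so that all 4 null values lay below all 4 wildtype values. The exact two-sided permutation test of the group means gave p = 0.0286, the smallest value that the 70 assignments of 8 arrays allow. In the limma fit across 11804 features the log2 difference was -0.95 (SE 0.15) and Gja1 ranked 2 by p-value, with an adjusted p of 0.340. Gja1 had 1 probe, whose position relative to the deleted part of the gene is not known here, and a probe outside that part would be a weaker check of the labels. The ratio in null hearts was 51.6% of that in wildtype hearts.

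**Figure D1:**
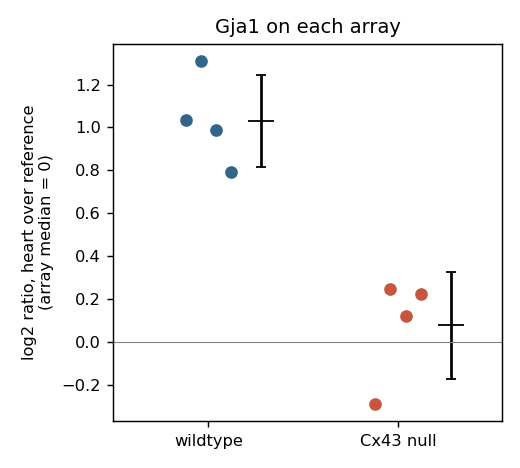
Log2 ratio of Gja1 in heart over reference on each array, with the array median at 0. Points are single arrays (4 wildtype, 4 Cx43 null) and the bars beside them show the group mean and SD, 1.03 ± 0.21 and 0.08 ± 0.25.

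The main comparison asked which genes differ in their transcript level when connexin43 is absent from the neonatal heart. Gja1 set aside, the named genes with the smallest p-values in each direction were the cDNA BB001228 and Slc2a1, with values 1.90-fold and 1.43-fold higher in null hearts, and Klf9, Cbr2 and Kctd6, with values 1.90-fold, 2.63-fold and 1.60-fold lower. None of them passed an adjusted p of 0.05 in limma, and 0 of 11804 features were called. At an unadjusted p under 0.05, 972 features were counted, 248 with a higher and 724 with a lower value in null hearts, where 590 would be counted with no change at all. Without centring of the arrays the same counts were 28 higher and 1364 lower, with the median difference of all features at -0.18 in place of -0.04. They were 181 higher and 451 lower without null replicate 2. A split of the arrays that mixed the genotypes counted 1219 features. The number of features called was also 0 with limma treat against 1.2-fold, and the genes named next did not pass the test. They are those with the smallest p-values among genes whose groups did not overlap.

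Among genes with higher values in null hearts, Slc2a1, which encodes the glucose transporter GLUT1, had a mean log2 ratio of 0.65 ± 0.13 in null hearts and 0.13 ± 0.09 in wildtype (SD, n = 4 each), a difference of 0.52 (SE 0.11, 1.43-fold, adjusted p = 0.370). Its 2 probes gave 0.46 and 0.58. The cDNA BB001228 had the largest difference of this group, 0.92 (SE 0.16, 1.90-fold, adjusted p = 0.370), and the cDNA 2210419I08Rik had 0.89 (SE 0.24) with 3 wildtype arrays measured. Loxl2, a lysyl oxidase that cross-links collagen, had 0.45 (SE 0.11), but its 2 probes read 0.74 and 0.17. Its difference was 0.16 without wildtype replicate 4, a drop that came from a probe lost to the filter. That array had the highest wildtype value of Loxl2, 0.48, and so did not raise the difference. Adgrg6, an adhesion receptor of the G protein-coupled family, had 0.75 (SE 0.19) over 3 arrays per group. Plekha2 had 0.58 (SE 0.13) and Card10, a scaffold of NF-kB signalling, 0.47 (SE 0.13), each with 3 wildtype arrays. Smaller differences stood at Ankzf1 (0.42, SE 0.10), Ldb1, a cofactor of LIM domain proteins (0.39, SE 0.10), and Myadm (0.37, SE 0.09). The 3 probes of Ankzf1 read 0.94, 0.33 and 0.12. Its difference was 0.11 without wildtype replicate 2, a drop that came from probes lost to the filter. On that array Ankzf1 read -0.15, against -0.29 to -0.21 on the other wildtype arrays, so the array itself did not raise the difference. By contrast, the 3 probes of Myadm read 0.35, 0.38 and 0.38.

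Among genes with lower values in null hearts, Klf9, a transcription factor induced by glucocorticoid and thyroid hormone, had a mean log2 ratio of -0.76 ± 0.22 in null hearts and 0.16 ± 0.31 in wildtype (SD, n = 4 each). Its difference was -0.92 (SE 0.17, adjusted p = 0.370), with -0.78 and -1.07 on its 2 probes. The stress-induced nuclear protein gene Nupr1 had -0.92 (SE 0.18), with -1.14 and -0.87 on its 2 probes. Cbr2, a carbonyl reductase abundant in lung, had the largest difference, -1.39 (SE 0.24) over 3 null and 4 wildtype arrays, followed by Cdc123 at -1.24 (SE 0.26). Fbxo2, which encodes an F-box protein that binds glycoproteins, had -0.85 (SE 0.17) over 3 null arrays. Baiap2, an adaptor between small GTPases and actin, had -0.71 (SE 0.15), the small GTPase gene Rasd2 -0.69 (SE 0.14) and Kctd6 -0.68 (SE 0.13). F3, which encodes tissue factor, the starter of the clotting cascade, had -0.61 (SE 0.12), and the ubiquitin ligase gene Trim2 had -0.56 (SE 0.11). The 4 null values of F3 had an SD of 0.019, against 0.23 in wildtype.

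The next question was whether genes of a shared function moved together. Genes of the extracellular matrix, the cell cycle, glycolysis and the hypoxia response had higher values in null hearts, by median log2 differences of 0.16, 0.17, 0.29 and 0.16. These medians were 0.16, 0.13, 0.13 and 0.10 without wildtype replicate 1, and smaller without centring of the arrays, as given below. Of the fixed gene lists and marker sets 26 had at least 5 measured members. With limma camera at a preset correlation of 0.01, 8 lists rose relative to the other genes in null hearts and 0 fell. With a correlation estimated for each list, 0 of these lists passed, and 0 passed fry, and 12 of the 35 splits of the arrays into 4 and 4 called at least 8 lists. No member of any of these lists passed over all genes.

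The extracellular matrix list gave the smallest p-value. Of its 31 measured members 28 had higher values in null hearts, with a median log2 difference of 0.16 (adjusted p = 2.93e-08, and adjusted p = 0.122 with an estimated correlation), and 0 passed adjusted over the list alone. Without centring the median was 0.02, against -0.18 for all features. Mfap2 and Mfap4, which encode microfibril proteins, had 0.67 (SE 0.18) and 0.42 (SE 0.14). The matricellular protein gene Sparcl1 had 0.52 (SE 0.18) and Fn1, which encodes fibronectin, 0.45 (SE 0.15). Averaged over the list, the log2 ratio was 0.72 ± 0.05 in null and 0.53 ± 0.07 in wildtype hearts (SD, n = 4 each). The microfibril gene Mfap5, a member of this list, went the other way at -0.55 (SE 0.22), and at -0.32 without wildtype replicate 1. Markers of fibroblasts, 6 of which another list also holds, had a median difference of 0.08 over 9 members and did not pass (adjusted p = 0.280), and without wildtype replicate 1 their median was -0.00039 (adjusted p = 0.720).

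The cell cycle list rose relative to other genes, with higher values for 32 of 42 measured members and a median log2 difference of 0.17 (adjusted p = 7.07e-08, and adjusted p = 0.167 with an estimated correlation). The count adjusted over the list alone was 0, and without centring the median was 0.03. The cyclin gene Ccnd3 had 0.36 (SE 0.12), Cdc20, which encodes an activator of the anaphase-promoting complex, 0.36 (SE 0.12), and Top2a, which encodes the topoisomerase of dividing cells, 0.44 (SE 0.16), or 0.26 without wildtype replicate 1, with 0.51 and 0.18 on its 2 probes. Cdkn1a, which encodes the cell cycle inhibitor p21, had -0.43 (SE 0.13), with all 4 null values below all 4 wildtype values, and -0.20 without wildtype replicate 4. The mean level of the list was 0.46 ± 0.06 in null and 0.32 ± 0.11 in wildtype hearts (SD, n = 4 each). Groups overlapped narrowly, with 0.4095 on wildtype replicate 2 and 0.4086 on null replicate 2.

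Glycolysis genes had a median difference of 0.29, with higher values for 13 of 15 members (adjusted p = 7.43e-07, and adjusted p = 0.196 with an estimated correlation). Slc2a1 was the 1 gene past the threshold adjusted over the list alone (adjusted p = 0.00769). The aldolase gene Aldoa had 0.41 (SE 0.14), the phosphofructokinase gene Pfkp 0.37 (SE 0.13) and the hexokinase gene Hk1 0.35 (SE 0.14), or 0.22 for Hk1 without wildtype replicate 1. The hypoxia response list, which shares Slc2a1 with glycolysis, had higher values for 10 of 14 members and a median of 0.16 (adjusted p = 9.04e-05, and adjusted p = 0.122 with an estimated correlation), and again 1 gene, Slc2a1, passed adjusted over the list alone. Bnip3, which encodes a mitochondrial protein induced by low oxygen, had 0.36 (SE 0.11), on both of its probes, Pdk1, which encodes a kinase that holds pyruvate dehydrogenase inactive, 0.44 (SE 0.20), and the oxygen sensor gene Egln1 0.21 (SE 0.10). Without wildtype replicate 1, whose mean glycolysis level was 0.014 against 0.30 to 0.48 on the other wildtype arrays, the median was 0.13 for glycolysis, below the 0.16 of the extracellular matrix list, and 0.10 for hypoxia, and without wildtype replicate 4 the hypoxia median was 0.09. Without centring, the glycolysis median was 0.11 and the hypoxia median -0.0025, against -0.18 for all features. The glycolysis level of wildtype replicate 4, 0.48, was above that of null replicate 1, 0.41, while hypoxia levels did not overlap between genotypes.

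**Figure D2:**
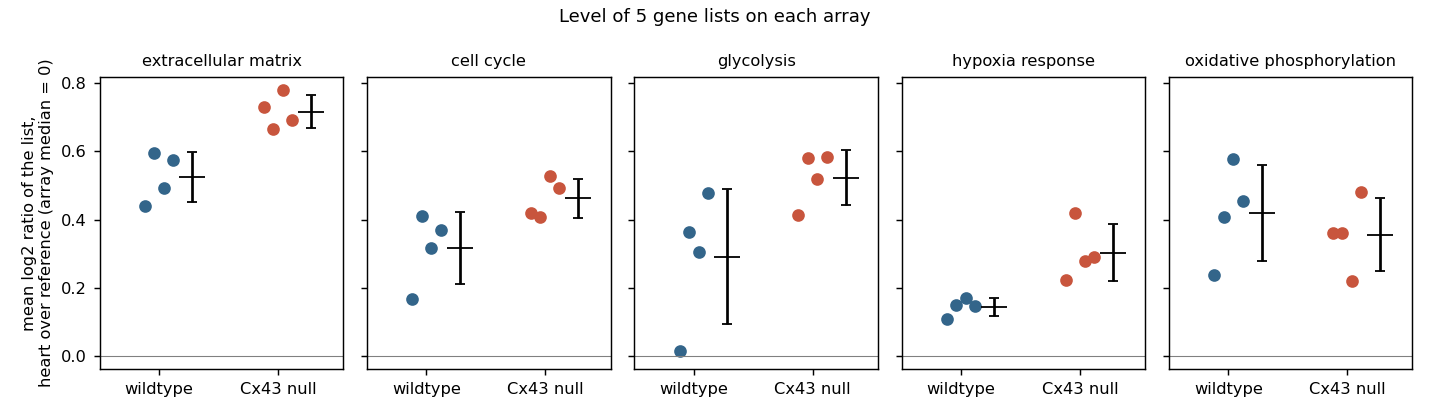
Mean log2 ratio of 5 gene lists in heart over reference on each array, with the array median at 0. Points are single arrays (4 per genotype), bars show the group mean and SD, and for the extracellular matrix the means are 0.53 in wildtype and 0.72 in null hearts.

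The cytoskeleton list rose relative to other genes with higher values for 27 of 39 members and a median of 0.09 (adjusted p = 0.000567, and adjusted p = 0.806 with an estimated correlation). The count adjusted over the list alone was 0, and without wildtype replicate 1 the list no longer passed (median 0.04, adjusted p = 0.219). Without null replicate 4 its median was 0.06 (adjusted p = 0.0110). The intermediate filament gene Vim had 0.63 (SE 0.22), the filamin gene Flna 0.39 (SE 0.15), the moesin gene Msn 0.29 (SE 0.11) and the Arp2/3 subunit gene Arpc2 -0.24 (SE 0.10), with -0.31, -0.37 and -0.04 on its 3 probes. Genes of the intercalated disc and of cell adhesion, the structures in which connexin43 resides, had higher values for 15 of 23 members and a median of 0.07 (adjusted p = 0.00808, and adjusted p = 0.152 with an estimated correlation), and 0 passed adjusted over the list alone. The zonula occludens gene Tjp1, whose product binds connexin43, had 0.23 (SE 0.11), the talin gene Tln1 0.22 (SE 0.10), Nrap 0.32 (SE 0.16) and the cadherin gene Cdh2 0.20 (SE 0.11). Without wildtype replicate 1 Tjp1, whose 2 probes read 0.11 and 0.41, had 0.07 and Cdh2 0.13, and without null replicate 3 Nrap had 0.16. Tjp1 also had 0.08 to 0.14 without wildtype replicate 2 or 4 or null replicate 2, 3 or 4. Its drop was thus not particular to 1 array, and a probe lost to the filter can enter it. This list no longer passed without wildtype replicate 3 (adjusted p = 0.0820) or null replicate 2 (adjusted p = 0.0650), and its median was 0.10 without wildtype replicate 2, 0.11 without null replicate 3 and 0.03 without null replicate 4. Without centring, its median was -0.08 and that of the cytoskeleton list -0.07, both above the -0.18 of all features. Mean levels of both lists overlapped between genotypes. On wildtype replicate 4 they were 0.38 for the intercalated disc and 0.20 for the cytoskeleton, against 0.36 and 0.11 on null replicate 1.

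Endothelial and erythroid markers passed camera at the preset correlation, but their mean levels overlapped between genotypes. Levels of the glycolysis, cell cycle, intercalated disc and cytoskeleton lists overlapped as well, and those of the extracellular matrix and hypoxia lists did not. Endothelial markers had higher values for 7 of 8 members, with a median of 0.15 (adjusted p = 0.00650, and adjusted p = 0.248 with an estimated correlation), among them Cav1 (0.26, SE 0.12), Flt1 (0.25, SE 0.14), Esam (0.24, SE 0.18) and Eng (0.18, SE 0.16, or 0.05 without wildtype replicate 3), although the 3 probes of Cav1 read 0.23, 0.60 and -0.06. The endothelial level of wildtype replicate 1, 0.74, was above those of all 4 null arrays (0.52 to 0.66). Erythroid markers had higher values for 8 of 11 members, with a median of 0.19 (adjusted p = 0.0109, and adjusted p = 0.851 with an estimated correlation), among them the embryonic globin gene Hbb-bh1 (0.35, SE 0.17), Rhag (0.25, SE 0.15), Slc4a1 (0.19, SE 0.16, or 0.12 without null replicate 2) and Car1 (0.18, SE 0.11). In neither set did a member pass adjusted over the list alone (0 of 8 and 0 of 11). The erythroid level was -0.45 on wildtype replicate 4, while wildtype replicates 2 and 3, at 0.13 and 0.07, were above null replicates 3 and 4, at -0.07 and -0.00037. Without centring the medians were -0.0072 and 0.05, against -0.18 for all features. The endothelial call was lost without wildtype replicate 2 (adjusted p = 0.169) or 3 (median 0.10, adjusted p = 0.0820), and without replicate 1 the median was 0.23 (adjusted p = 0.00100). The erythroid call was lost without wildtype replicate 2 (adjusted p = 0.0523), 3 (adjusted p = 0.0820) or 4 (median -0.05, adjusted p = 0.945) and without null replicate 1 (adjusted p = 0.0812) or 2 (adjusted p = 0.0836).

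**Figure D3:**
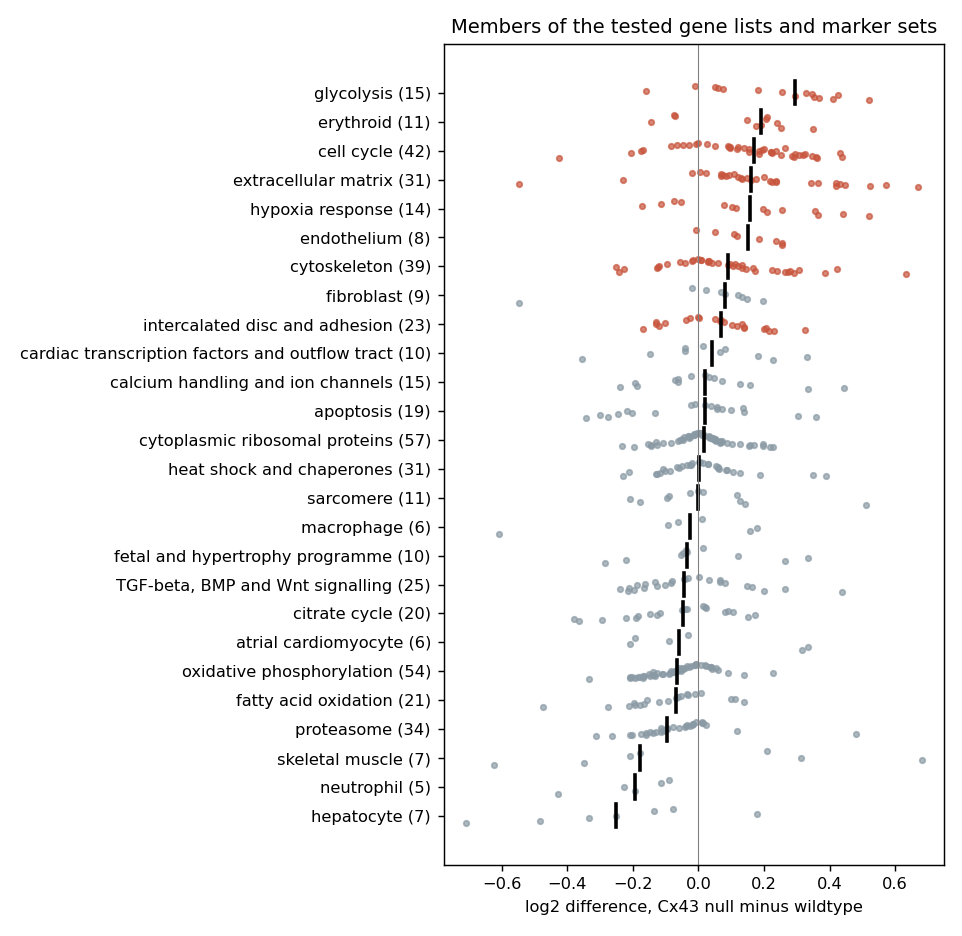
Log2 difference between Cx43 null and wildtype hearts for each measured member of the 26 tested lists, whose number of members stands in brackets. Points are genes, black bars are list medians, and red marks the 8 lists that passed camera with a preset correlation, with medians between 0.07 and 0.29.

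Genes of energy metabolism in mitochondria did not pass. Of 54 oxidative phosphorylation genes 42 had lower values in null hearts, with a median of -0.06 (adjusted p = 0.427), and the complex I genes Ndufb3 (-0.33, SE 0.13), Ndufb9 (-0.21, SE 0.11) and Ndufs4 (-0.17, SE 0.11, or -0.11 without wildtype replicate 3) and the complex III gene Uqcrc2 (-0.19, SE 0.10) stood lowest by p-value. Without wildtype replicate 1 this list passed as lower, with a median of -0.15 (adjusted p = 0.000687), as it did after a correction for the trend of the difference on the mean ratio (median -0.09, adjusted p = 0.00226) and without centring (median -0.22, adjusted p = 0.00363). With an estimated correlation over all arrays it had adjusted p = 0.851, as did the proteasome, ribosomal and heat shock lists below, and that estimate was not run with an array left out. Fatty acid oxidation genes had lower values for 17 of 21 members (median -0.07, adjusted p = 0.284; without wildtype replicate 1 -0.11, adjusted p = 0.0751), with the carnitine carrier gene Slc25a20 at -0.48 (SE 0.19), or -0.29 without null replicate 1, and -0.24 and -0.71 on its 2 probes. Citrate cycle genes had lower values for 12 of 20 (median -0.05, adjusted p = 0.599; without wildtype replicate 1 -0.12, adjusted p = 0.121), with Pdhb at -0.36 (SE 0.14) and Got2 at -0.29 (SE 0.12). Proteasome genes had lower values for 28 of 34 (median -0.10, adjusted p = 0.284), with Psmb4 at -0.31 (SE 0.11) and at -0.21 without wildtype replicate 3, and passed as lower without wildtype replicate 1 (adjusted p = 0.0171) or without centring (adjusted p = 0.0109). Cytoplasmic ribosomal protein genes had a median of 0.02 over 57 members (adjusted p = 0.0576), and passed as higher without wildtype replicate 3 (median 0.11, adjusted p = 4.16e-06) or null replicate 3 (median 0.08, adjusted p = 0.000107), whereas without wildtype replicate 1 the median was -0.07 (adjusted p = 0.500). Heat shock and chaperone genes had a median of 0.0011 over 31 members (adjusted p = 0.284) and passed as higher without wildtype replicate 4 (median 0.07, adjusted p = 0.0105), whereas without wildtype replicate 1 the median was -0.04 (adjusted p = 0.842).

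The lists closest to contraction, rhythm and heart development did not pass either. The sarcomere list had a median of -0.0015 over 11 members (adjusted p = 0.284), with Ldb3, a Z-disc gene, at 0.51 (SE 0.19). Calcium handling and ion channel genes had 0.02 over 15 members (adjusted p = 0.284). Among them the kinase gene Camk2d stood at 0.44 (SE 0.19), Atp2a2, which encodes the calcium pump of the sarcoplasmic reticulum, at -0.24 (SE 0.11) and its regulator gene Pln at -0.19 (SE 0.10), and without null replicate 1 Atp2a2, whose 3 probes read -0.03, -0.35 and -0.34, stood at -0.16. Cardiac transcription factor and outflow tract genes had 0.04 over 10 members (adjusted p = 0.284), with Nrp1 at 0.23 (SE 0.12; 0.14 without null replicate 3) and Sema3c, a guidance cue of outflow tract cells, at -0.36 (SE 0.20; -0.14 without wildtype replicate 1). The fetal and hypertrophy programme had -0.04 over 10 members (adjusted p = 0.690), with Nppa, the atrial natriuretic peptide gene, at 0.33 (SE 0.31), and at 0.03 without wildtype replicate 2. TGF-beta, BMP and Wnt genes had -0.05 over 25 members (adjusted p = 0.633) and apoptosis genes 0.02 over 19 (adjusted p = 0.690). Without wildtype replicate 1 the medians were -0.06 for sarcomere, 0.08 for calcium handling, 0.03 for cardiac transcription factors, -0.05 for the fetal programme, -0.02 for TGF-beta and -0.02 for apoptosis, and 0 of these 6 lists passed. The median and the test differed in sign for the sarcomere, fetal programme and TGF-beta lists and for atrial and macrophage markers, and for apoptosis the mean was -0.02. Of the 17 other connexin and pannexin genes 4 were on the array and 0 had values on 3 arrays of each group.

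Of the remaining cell types, atrial markers had a median of -0.06 over 6 members (adjusted p = 0.599), macrophage markers -0.03 over 6 (adjusted p = 0.690), neutrophil markers -0.19 over 5 (adjusted p = 0.284), skeletal muscle markers -0.18 over 7 (adjusted p = 0.881) and hepatocyte markers -0.25 over 7 (adjusted p = 0.284). Without wildtype replicate 1 the hepatocyte markers passed as lower, with a median of -0.44 (adjusted p = 0.0419), at the preset correlation alone, as too few were measured on all arrays for an estimate. Without that array the medians were -0.02 for atrial, 0.05 for macrophage, -0.14 for neutrophil and -0.15 for skeletal muscle markers, and none of these passed. Sets with fewer than 5 measured members were not tested as sets. Of lung epithelium markers 2 were measured, Scgb1a1 at -0.59 (SE 0.15) and Sftpc at -0.63 (SE 0.19). Both passed adjusted over the list alone (adjusted p = 0.00474 and 0.00611), a slight adjustment with 2 members, and neither over all genes (adjusted p = 0.510 and 0.550). They were among the genes with the lowest ratios against the reference, given below. All of those, from several organs, had lower values in null hearts. Median differences were -0.06 for 4 smooth muscle markers, -0.09 for 3 epicardial markers and -0.28 for 2 markers of nerve and glia, with 0 genes past the threshold adjusted over the list alone. Single members of these sets changed sign with 1 array left out. Cnn1 went from -0.10 to 0.11 without wildtype replicate 2, Krt8 from -0.09 to 0.04 without null replicate 2, and Nefl from -0.25 to 0.17 without null replicate 3. The 1 measured lymphocyte marker, Cd79b, stood at -0.30 (SE 0.26), the 1 fat marker, Ucp1, at 0.33 (SE 0.20; 0.15 without wildtype replicate 1), and the 1 measured ventricular marker was Gja1.

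Levels against the reference describe how the neonatal heart differs from a mix of adult tissues and were not tested, since dyes were not swapped. In wildtype hearts the mean log2 ratio of the sarcomere list was 0.79 ± 0.10, and that of hepatocyte markers was -1.76 ± 0.31 (SD, n = 4 each). In null hearts they were 0.82 ± 0.11 and -2.03 ± 0.32 (SD, n = 4 each).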

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

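The test of a wrong label for wildtype replicate 1 was chosen after its result was seen. Single arrays lay far from the other 3 of their group, by a gap beyond Dixon's critical value at 95%, in 15 of 332 groups of 4 values, where about 1 in 20 does so by chance. On wildtype replicate 1 these were the log2 ratios of Aldoa (0.12), Mfap4 (-0.34), Top2a (-0.35), Mest (3.36) and Pla2g1b (-3.15). On wildtype replicate 3 they were Rasd2 (-0.077) and Pdlim5 (0.45), on replicate 2 Bves (1.06) and on replicate 4 Cdkn1a (0.70). Null replicate 3 read apart from its group for Cav1 (0.72), Fstl1 (1.97), Nrap (1.00) and Nrp1 (1.09), null replicate 4 for Mpo (-0.26) and null replicate 1 for Msln (0.34).

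Wildtype replicate 1 stood apart as a whole: it had an array weight of 0.249 and a value of -31.5 on the first principal component, which held 38.0% of the variance and on which the other 7 arrays lay between 0.56 and 12.9. Over the 10320 spots with a value on all arrays its median rank correlation with the others was 0.576, against at least 0.663 for each other array, and this argues against its lower number of spots as the whole cause. After each block of spots was centred the value was 0.573 against at least 0.638, which argues against offsets between blocks as the cause. Blocks accounted for little of the spread on this array (R2 of 0.021), so centring could change little, and uneven signal within blocks was not tested. Its Gja1 ratio exceeded the highest null ratio by 0.79 on the log2 scale, more than the SD of the null values (0.25), which argues against a null pool under a wildtype label as far as the Gja1 probe can show. Brightness and background of the spots are not in the values used here and stay open, and no biological explanation was tested, since the labels set this pool apart in nothing.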

How the results depend on the processing

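Centring within blocks, the median over shared spots, the plain mean of probes, the trend correction and the preset correlation on fully measured genes were chosen after seeing the data. Gja1 stayed lower under every setting and array left out, with log2 differences from -1.11 to -0.83. The count of genes past adjusted p 0.05 in limma stayed at 0 under each of them, at adjusted p 0.1 and with treat, and the smallest adjusted p of any feature was 0.128, with array weights (up to 0.761 in other settings, treat aside); no named gene passed in any setting in which it was measured; an unadjusted p of 0.05 with a 1.5-fold change gave 148 (29 higher, 119 lower). At unadjusted p under 0.05, counts moved by over 1.5 times without centring (28 higher, 1364 lower), with single probes (380 higher) and over features on all 8 arrays (440 lower), where fewer features were tested; for the other settings the cause was not tested. With 1 array left out, counts ranged from 167 to 274 higher and from 451 to 636 lower; the lowest were 167 without null replicate 3 and 451 without null replicate 2. The 8 gene lists became 0 with an estimated correlation, and 0 with fry. Over the same fully measured genes the preset correlation called 7, so the change did not come from the smaller set of genes. The size of the correlation alone did not account for it either. For the intercalated disc list the estimate was 0.018, close to the preset 0.01, and its camera adjusted p still went from 0.0033 to 0.152. Camera with an estimated correlation also uses far fewer degrees of freedom. The p-values of a list under both settings therefore differ in more than the correlation. Other settings called 7 to 10 lists, and arrays left out in turn gave 6 to 10. Erythroid markers were not called over features on all 8 arrays (adjusted p = 0.264), with the preset correlation on the fully measured named genes (adjusted p = 0.132) or over features on at least 2 arrays per group (adjusted p = 0.0510), where ribosomal protein genes were called as higher (adjusted p = 0.0456), and the intercalated disc list was not called after scaling to equal spread (adjusted p = 0.0664). The sarcomere level in wildtype hearts ranged from 0.72 to 0.84 and the hepatocyte level from -1.90 to -1.65. Same-numbered pools did not deviate together (r = -0.24, -0.01, -0.25 and -0.02 across features), and no wildtype pool correlated best with the null pool of its number. This gave no sign of pairing, but a small shared effect could be missed, and the labels leave the meaning of the numbers open. With the replicate block 0 genes passed, 198 higher and 530 lower counted at unadjusted p under 0.05, and 8 lists were called. Signal over background is not in the values used here, and its limit on low ratios is unknown.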

Other observations

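The trend correction of the gene lists was chosen after seeing the data, and the genes of the paragraphs on levels against the reference were chosen after their values were seen, as the named genes with the highest and lowest mean ratio over all arrays.

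Mest, H19, Afp and Grb10 were among the genes with the highest ratios of neonatal heart over the adult reference. In wildtype hearts Mest was 6.65-fold, H19 5.16-fold and Grb10 3.81-fold above the reference, with log2 ratios of 2.73 ± 0.42, 2.37 ± 0.55 and 1.93 ± 0.37 (SD, n = 4 each), and the transcription factor gene Plagl1 had 1.75 ± 0.22. Afp, which encodes the fetal plasma protein alpha-fetoprotein, was 4.56-fold above (2.19 ± 0.11). Of heart muscle genes, the sodium-calcium exchanger gene Slc8a1 had 1.88 ± 0.21, the natriuretic peptide gene Nppb 1.65 ± 0.11, Bves 1.47 ± 0.28 and the sarcoplasmic reticulum gene Srl 1.73 ± 0.41, and Fstl1 had 1.58 ± 0.11. In null hearts H19 had 3.08 ± 0.12 and Grb10 2.54 ± 0.21 (SD, n = 4 each), and their differences from wildtype did not pass (adjusted p = 0.553 and 0.550 in limma). Of the other genes of this paragraph, Srl (-0.29), Plagl1 (-0.13) and Nppb (-0.05) had lower values in null hearts. Mest, Afp, Slc8a1, Bves and Fstl1 had higher ones, and none passed. The null values of Plagl1 were widely scattered (1.62 ± 1.03, SD, n = 4), so that its direction is uncertain.

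The lowest ratios belonged to genes of adult organs. The sperm chromatin gene Tnp1 was 9.38-fold below the reference in wildtype hearts, the lung genes Scgb1a1 and Sftpc were 5.82-fold and 5.45-fold below, and the liver genes Serpina1e, Alb, Pzp, Mup9 and Apoa1 were 5.72-fold, 5.41-fold, 4.97-fold, 4.66-fold and 4.43-fold below. Clps, which encodes pancreatic colipase, and Pla2g1b, which encodes pancreatic phospholipase A2, were 6.85-fold and 5.80-fold below, although the labels do not list pancreas among the tissues of the reference. Of these 10 genes, each had a lower ratio in null than in wildtype hearts, with log2 differences from -0.74 (Pzp) to -0.19 (Clps), and none passed (smallest adjusted p = 0.510 in limma). Across the tested features, which are not independent replicates, the difference between genotypes correlated with the mean ratio (r = 0.353).

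The 8 lists that rose in null hearts are a pattern that noise may account for. In 12 of the 35 splits of the 8 arrays into 4 and 4, the real one included, at least 8 lists were called. The real split had 8 and another up to 12, so chance cannot be excluded. When a correlation was estimated for each list, 0 of the 8 were called. The estimates ran from 0.018 (intercalated disc) to 0.34 (erythroid), against the preset 0.01. Even the list with an estimate near the preset lost its call. The estimated setting also uses far fewer degrees of freedom, so this loss cannot tell correlated noise from a weaker test. Without wildtype replicate 1, 7 of the 8 were still called as higher, which argues against that array as the whole cause, with cytoskeleton the exception. After the correction for the trend on the mean ratio 6 of the 8 were called as higher, which argues against an unequal stretch of the ratios as the whole cause, although intercalated disc (median 0.07 before and 0.04 after, adjusted p = 0.334) and endothelium (0.15 and 0.09, adjusted p = 0.194) were not. Chance, correlated noise and an effect of the genotype stay open.

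The count of genes past adjusted p 0.05 was 0 in all 35 splits, the real one included, and a count of 0 is reached by any split, so that it decides nothing. At unadjusted p under 0.05, 2 of the 35 splits, the real one included, counted at least the 972 features of the real one, and the highest other, wildtype replicates 1 and 4 with null replicates 2 and 3 against the rest, had 1219, so chance could not be excluded for that count.

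Null alleles made in another mouse strain can carry a stretch of that strain around the deleted gene, and its variants could then differ between genotypes. Of the 187 measured genes nearest to Gja1 by order in the GRCm38.p6 gene table, 87 on one side and 100 on the other, 19 (10.2%) had an unadjusted p under 0.05, against 616 of 7312 other genes (8.42%). The odds ratio was 1.23 (95% interval 0.717 to 2.00, Fisher's exact test p = 0.423), an interval too wide to argue for or against such a stretch. The window took up to 100 measured genes per side, and a shorter stretch would be diluted among them.

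The feature with the smallest p-value is an unnamed probe, probe_49, with a log2 ratio of 1.21 ± 0.24 in 4 null pools and 0.15 ± 0.17 in 3 wildtype pools, a difference of 1.06 (SE 0.15, adjusted p = 0.340 in limma). It was chosen after its values were seen. The median SD of a feature within a group was 0.145 in null and 0.187 in wildtype pools over 8238 features, 16 of 35 splits were at least as uneven, and without replicate 1 the wildtype value was 0.134. Spots with a value on all null and no wildtype array numbered 4, and spots with a value on all wildtype and no null array 27, where the 70 assignments of arrays gave a median of 4 and a highest count of 283.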
